A study of Mus musculus with 4 samples.

How the data were processed

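RNA sequencing values from 4 mouse libraries were used, 2 from wild-type and 2 from Stk40-/- embryonic stem cells at day 3 of mesoderm differentiation. Groups and replicate numbers were taken from the sample titles. Per the labels, polyadenylated RNA was enriched and read in pairs of 100 bases on one instrument or 150 bases on another, and which library was read on which is not given in the sources used here. Read length and instrument could therefore differ between or within groups, and no batch term could be fitted.

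The deposited values were TPM per gene, per the file headers, and each column summed to 1000000 over 51826 genes. CASAVA 1.7 and Salmon 0.8.2 are named per the submitters' processing notes, with no parameters. The build named there is hg38, a human build, although the gene IDs in the table are mouse Ensembl IDs, so the annotation used by the authors is not given in the sources used here. TPM keeps no sequencing depth, so the precision of a single value is unknown. Salmon divides reads among similar transcripts, and values of genes with near-identical copies and of short RNAs are less certain for that reason. A rise in a few abundant RNAs lowers the TPM of other genes in the same library. There were 0 per-sample columns left unused.

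Positions and transcript lengths came from GENCODE vM21 on GRCm38, matched by Ensembl ID without its version. Of the IDs, 51633 matched in this way and 47648 matched with the version. The length of a gene was that of its longest transcript.

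Genes with a mean of at least 1 TPM were tested (15739 genes) on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend, 2 against 2 libraries, no replicate block, and Benjamini-Hochberg adjustment with a threshold of 0.05. The smallest p that an exact permutation test of 2 against 2 libraries can give is 0.333, so single values such as library composition are given per library without a call. A total of 39 gene lists was fixed before the data were examined, as were the tests and the rule for named genes. The 37 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation, ranks, and fry were alternatives. The fry p tests whether the genes of a list move on balance one way, and its mixed p whether they change in either direction. With an estimated correlation 0 lists passed (smallest adjusted p = 0.456), with fry 1 list passed, and with the mixed fry test 18 passed. Of the lists called by camera, those of the primitive streak, glycolysis and hypoxia, cholesterol synthesis and neuroectoderm did not pass the mixed test. Those that passed it without a camera call were general pluripotency, blood and endothelial, AP-1 subunit, JUN-associated, immediate early, imprinted, primordial germ cell, p53, heat shock, integrated stress response and methylation-silenced germline genes. The lists of genes active in cells resembling the embryo after its first division and of sex chromosome genes had too few tested members. The direction in camera differed from the sign of the mean for definitive endoderm and COP1 genes, from that of the median for AP-1 subunit and imprinted genes, and from both for heat shock and extraembryonic endoderm genes. Across the lists 75 genes occur in more than 1.

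The named genes were Stk40 and Jun, 12 genes per direction with the largest fold change among those that passed with a mean of at least 5 TPM and no overlap of groups, and from each list described up to 4 members with the smallest unadjusted p, plus 20 mesoderm and pluripotency genes in any case. Because no gene passed, the 12 per direction were filled by the smallest unadjusted p and are not calls. One gene that the rule names is not reported here. Regions of chromosomes were examined after the values were seen, over protein-coding genes with a mean of at least 5 TPM.

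The procedure was tested on simulated data for the Stk40-/- against wild-type comparison, with 200 of 15739 genes changed and independent noise of the size fitted here. limma recovered 0% of genes changed 2-fold, 39% of those changed 4-fold and 60% of those changed 8-fold. With every member of 1 list at a time shifted by -1 on the log2 scale, camera with the preset correlation found 37 of 37 lists and with an estimated correlation 0 of 37. Among 740 tests of lists with no change it called 0 either way. The simulated genes were independent, so this does not show how the preset correlation behaves when genes of a list vary together. In the real data the estimated correlation was 0.464 for primitive streak and 0.234 for mesenchymal genes. It was 0.386 for glycolysis and hypoxia and 0.659 for cholesterol synthesis. All lie far above the preset 0.01, so the preset p values of these lists may be too small. Among the other called lists the estimate ran from -0.090 for BMP targets to 0.185 for neuroectoderm.

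The alternatives were pseudocounts of 0.1 and 0.01, filters at a mean above 0 and of at least 5 TPM, quantile normalization, median-of-ratios rescaling, TPM recomputed without mitochondrial and ribosomal protein genes, empirical Bayes without trend or robust, the replicate number as a block, limma's treat against a fold of 1.5, a minimum absolute log2 fold change of 1, and leaving out each library. Chosen after seeing the data were TPM recomputed over protein-coding genes alone (also with robust moderation), leaving out chromosome 16 and the first 10 Mb of X, and removing a trend on transcript length from each library. The settings of the empirical Bayes step do not enter camera and were not counted for the lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

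The lists not described with the results had these camera adjusted p values: 0.0543 for Nodal and activin targets, 0.0634 for immediate early genes, 0.169 for germline genes silenced by methylation, 0.179 for FGF and ERK targets, 0.179 for apoptosis genes, 0.179 for primordial germ cell genes, 0.382 for the JNK and MAPK pathway, 0.425 for replication-dependent histones, 0.477 for imprinted genes, 0.650 for mitochondrially encoded genes, 0.670 for Notch and somite clock genes, 0.670 for heat shock and unfolded protein response genes, 0.694 for p53 targets and 0.695 for the integrated stress response.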

Results

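Gene expression was measured by RNA sequencing in mouse embryonic stem cells directed towards mesoderm and collected at day 3 of differentiation. The protocol exposed the cells to BMP4 at 10 ng/ml for 2 days and then to the GSK3 inhibitor CHIR99021 at 1 uM with 0.5% DMSO until collection. There were 2 wild-type libraries and 2 libraries from cells lacking Stk40 (Stk40-/-), which encodes a pseudokinase. The deposited values were TPM, a transcript abundance scaled for transcript length and library size, for 51826 genes, of which 24265 were at 0 in all 4 libraries. The sequencing depth of each library is unknown from these values, so no counting interval is given. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each genotype may come from 1 line, so any difference between the groups may be one between lines rather than an effect of Stk40 loss. Values are means ± SD in TPM with n = 2 per group, and fold changes are log2 values of Stk40-/- against wild type on the log2(TPM + 1) scale, which understates the change of low genes. The median fold change of all tested genes was 0.065. Of 9713 protein-coding genes with a mean of at least 5 TPM, outside the regions of X and chromosome 16 described below, 3548 were negative. Positive signs were therefore the more common, and the counts of signs below are to be read against that share.

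The targeted gene was examined first, as a check of the labels. Stk40 (ENSMUSG00000042608.15; GRCm38 chromosome 4, 126103957 to 126141029) was at 28.9 and 39.9 TPM in the wild-type libraries and at 3.54 and 3.17 TPM in the Stk40-/- libraries. Its log2 fold change was -3.01 (SE 0.21), with a limma adjusted p = 0.139, so it did not pass the threshold of 0.05 despite lying far below both wild-type libraries. Over the alternatives run its adjusted p ranged from 0.0507 to 0.505. The series asks how loss of Stk40 affects the c-JUN protein and mesoderm formation. Jun (ENSMUSG00000052684.4; chromosome 4, 95049034 to 95052222), which encodes c-JUN, had 23.6 ± 3.49 TPM in wild type and 20.3 ± 2.13 TPM in Stk40-/- cells, with overlapping groups (log2 fold change -0.20, SE 0.17, limma adjusted p = 0.640). With 1 library left out at a time, the log2 fold change of Jun ranged from -0.35 to -0.06. Protein was not analysed here.

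Genes of the primitive streak and nascent mesoderm were lower as a group in Stk40-/- cells. Of the 20 genes in this list 13 were tested, all 13 had negative fold changes, and in 11 both Stk40-/- libraries lay below both wild-type libraries. The median log2 fold change was -0.93. T, the brachyury transcription factor of the streak, had 780 ± 347 TPM in wild type and 286 ± 97.7 TPM in Stk40-/- cells (log2 fold change -1.41, SE 0.40). The activin antagonist Fst had 101 ± 26.4 and 38.1 ± 3.11 TPM, and the growth factor gene Fgf8 90.2 ± 10.8 and 47.0 ± 6.72 TPM, in the same order. The ligand gene Apln was at 17.0 and 14.6 TPM in wild type and at 10.1 and 7.37 TPM in Stk40-/- cells. The homeobox gene Mixl1 was at 24.7 and 6.77 TPM in wild type and at 2.06 and 1.71 TPM in Stk40-/- cells. Eomes had overlapping groups (3.14 ± 1.09 and 2.67 ± 0.221 TPM). The list passed camera with a preset correlation (adjusted p = 2.08e-07), but not with an estimated one (adjusted p = 0.456 with an estimated correlation). In limma 0 members passed over all genes tested and 7 passed when adjusted over the list alone. The same 13 genes also differed between replicates, with a median log2 difference of -0.73 from wild-type library 1 to library 2 and of -0.24 between the Stk40-/- libraries.

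The caudal Cdx and Hox genes, which pattern the posterior body axis, were lower as a group in Stk40-/- cells. Of 10 tested members 9 had negative fold changes, with a median log2 fold change of -1.19. Cdx1 had 27.9 ± 0.481 TPM in wild type and 7.83 ± 1.90 TPM in Stk40-/- cells, Cdx2 had 10.1 ± 1.45 and 1.18 ± 0.396 TPM, Hoxb1 had 28.5 ± 13.7 and 3.85 ± 0.334 TPM, and Hoxb2 had 7.63 ± 0.880 and 2.24 ± 0.969 TPM. The list passed camera (adjusted p = 2.08e-07; adjusted p = 0.456 with an estimated correlation), and in limma 0 members passed over all genes and 5 adjusted over the list alone. The size depended on the filter on low values: the list's mean difference from other genes was -1.29, and -0.62 when all genes above 0 TPM were tested, and at a mean of at least 5 TPM too few members were left to test. Targets of Wnt signalling were lower as a group (18 tested, 13 negative, median -0.51, camera adjusted p = 0.000105), as were targets of BMP signalling (12 tested, 8 negative, median -0.44, camera adjusted p = 0.00213). Both had adjusted p = 0.456 with an estimated correlation. Adjusted over the list alone, 2 Wnt targets passed in limma, Cdx1 and Cdx2, and 3 BMP targets, Cdx1, Id1 and Gata2. Among Wnt targets that did not pass, the feedback target Axin2 had 34.1 ± 5.99 and 23.1 ± 2.95 TPM and Notum 4.86 ± 1.19 and 1.03 ± 0.665 TPM. The BMP target Id1 had 42.8 ± 5.72 and 19.6 ± 3.60 TPM, and Gata2 8.28 ± 1.30 and 1.25 ± 0.245 TPM. Cdx1 and Cdx2 belong to more than 1 of these lists, so the lists are not independent. The BMP call was lost without wild-type library 2 (camera adjusted p = 0.161).

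Mesenchymal genes were also lower as a group. Of 13 tested genes linked to the epithelial to mesenchymal transition, 12 had negative fold changes (median -0.58, camera adjusted p = 6.49e-05; adjusted p = 0.456 with an estimated correlation), and 0 passed limma adjusted over the list alone. The same genes differed between the wild-type libraries by a median of -0.46 from library 1 to library 2, and the list's mean difference from other genes, -0.51 with all libraries, was -0.33 without wild-type library 1 and -0.70 without wild-type library 2. Vim, which encodes vimentin, had 456 ± 124 TPM in wild type and 229 ± 4.81 TPM in Stk40-/- cells, and the fibronectin gene Fn1 had 79.5 ± 19.5 and 51.9 ± 3.26 TPM, with a log2 fold change of -0.59 that was -0.34 without wild-type library 1. Cdh2, the N-cadherin gene, had 27.0 ± 13.2 and 13.4 ± 0.0470 TPM, and its log2 fold change of -0.87 was -0.37 without wild-type library 1 and -1.37 without wild-type library 2. Cdh1, the E-cadherin gene, had 266 ± 3.38 and 327 ± 3.25 TPM, but the list of epithelial junction genes went both ways (23 tested, 13 positive and 10 negative, camera adjusted p = 0.727). Markers of feeder fibroblasts, on which the stem cells had been kept before differentiation, were lower too (16 tested, 13 negative, median -0.29, camera adjusted p = 0.000716; adjusted p = 0.456 with an estimated correlation), and this was the only 1 of 37 lists to pass the directional fry test (adjusted p = 0.0275). Its mean difference from other genes was -0.55, -0.35 without wild-type library 2 and -0.94 with a pseudocount of 0.01. Its members include genes that mesenchymal cells express in general, such as Acta2 (13.0 ± 1.79 and 3.79 ± 1.13 TPM) and Tagln (372 ± 18.2 and 275 ± 9.51 TPM), the 2 that passed adjusted over the list alone, and Col1a1 was low in both groups (7.13 ± 0.219 and 3.85 ± 0.156 TPM). Trophoblast markers were lower as a group (12 tested, 10 negative, median -0.56, camera adjusted p = 0.000105; adjusted p = 0.456 with an estimated correlation). Of its members 1, Cdx2, passed adjusted over the list alone. Cdx2 is also a member of the Cdx and Hox list and of the Wnt target list, so these lists are not independent. Ascl2 had 3.93 ± 0.0137 and 1.05 ± 0.298 TPM and Krt8 599 ± 175 and 384 ± 35.0 TPM, and the log2 fold change of Krt8, -0.61, was -0.31 without wild-type library 1.

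Genes of glycolysis and the hypoxia response were higher as a group in Stk40-/- cells. All 23 were tested and all 23 had positive fold changes, with a median log2 fold change of 0.28. The lactate transporter gene Slc16a3 had 315 ± 18.8 TPM in wild type and 535 ± 16.1 TPM in Stk40-/- cells, Eno1 2226 ± 85.4 and 2748 ± 1.88 TPM, and Bnip3 101 ± 8.60 and 144 ± 0.555 TPM. Pfkl was at 88.6 and 97.6 TPM in wild type and at 163 and 137 TPM in Stk40-/- cells. The list passed camera (adjusted p = 0.000167, and adjusted p = 0.502 with a correlation estimated at 0.386). In limma 0 members passed over all genes and 9 adjusted over the list alone. Genes of cholesterol synthesis were higher as a group (20 tested, 19 positive, median 0.29, camera adjusted p = 0.00435). With a correlation estimated at 0.659 the camera adjusted p was 0.697. In limma, however, 0 members passed over all genes or adjusted over the list alone. Hmgcs1 had 254 ± 12.7 and 358 ± 87.5 TPM, and Dhcr7 80.7 ± 8.38 and 125 ± 33.9 TPM. Without Stk40-/- library 1 the log2 fold change of Hmgcs1 went from 0.47 to 0.22 and that of Dhcr7 from 0.61 to 0.33, and without Stk40-/- library 2 that of Hmgcs1 was 0.73. The list's call was lost without wild-type library 1 (adjusted p = 0.104) and without Stk40-/- library 1 (adjusted p = 0.282). The median difference between the Stk40-/- libraries over these genes was -0.45, larger in size than the genotype median, and the mean difference from other genes was 0.29 with all libraries, 0.11 without Stk40-/- library 1 and 0.47 without Stk40-/- library 2.

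Genes of the primed epiblast, the state that precedes germ layer formation, were higher as a group in Stk40-/- cells (13 tested, 10 positive, median 0.46, camera adjusted p = 0.0287; adjusted p = 0.456 with an estimated correlation). The transcription factor genes Otx2 (3.88 ± 0.429 and 17.9 ± 7.13 TPM), Zic2 (34.3 ± 7.95 and 83.7 ± 8.91 TPM) and Pou3f1 (17.9 ± 0.229 and 33.1 ± 0.723 TPM) passed limma adjusted over the list alone. Neuroectoderm genes were higher as a group (10 tested, 10 positive, median 0.51, camera adjusted p = 0.0308; adjusted p = 0.479 with an estimated correlation). Sox3 had 18.3 ± 6.04 and 27.5 ± 5.18 TPM, and Tubb3 was at 2.66 and 3.97 TPM in wild type and at 4.84 and 11.5 TPM in Stk40-/- cells. The primed epiblast call was lost without wild-type library 1 (adjusted p = 0.213), without Stk40-/- library 1 (0.111) and without Stk40-/- library 2 (0.0610). In limma 0 neuroectoderm genes passed over all genes or adjusted over the list alone. The log2 fold change of Tubb3, 1.00 with all libraries, was 0.45 without Stk40-/- library 2 and 1.55 without Stk40-/- library 1, and that of Sox3, 0.59, was 0.26 without wild-type library 1 and 0.91 without wild-type library 2. The neuroectoderm call was lost without wild-type library 1 (adjusted p = 0.302), without wild-type library 2 (0.0536), without Stk40-/- library 2 (0.265) and with filters at a mean above 0 TPM (0.154) and of at least 5 TPM (0.164). The list's mean difference from other genes was 0.43, and it was 0.23 without Stk40-/- library 2 and 0.21 with the filter at a mean above 0 TPM. The neuroectoderm genes also differed between replicates, by a median of 0.32 from wild-type library 1 to library 2 and of 0.41 between the Stk40-/- libraries.

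**Figure D1:**
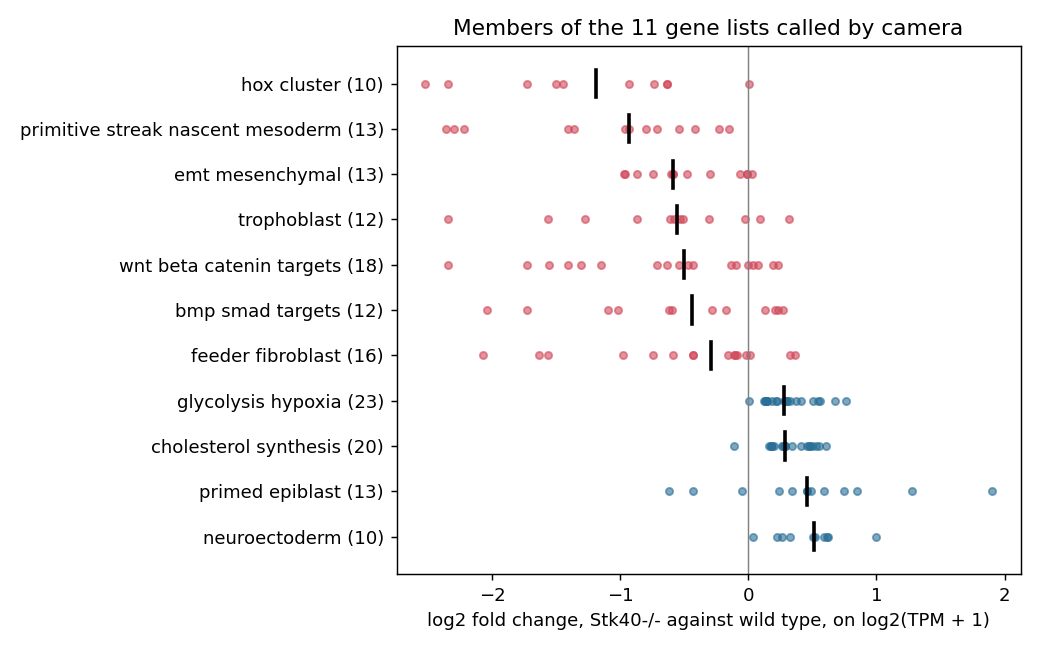
Log2 fold changes of Stk40-/- against wild type on log2(TPM + 1), 1 point per tested gene, for the 11 gene lists called by camera with a preset correlation, with the number of tested genes in parentheses and the list median as a black bar. The medians run from -1.19 for the Cdx and Hox genes to 0.51 for neuroectoderm.

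Pluripotency lists did not pass camera, and general pluripotency genes passed the mixed fry test, which asks for change in either direction (adjusted p = 0.0254). Pou5f1 had 422 ± 72.8 TPM in wild type and 419 ± 65.8 TPM in Stk40-/- cells, Nanog had 123 ± 13.5 and 193 ± 37.5 TPM, and Sox2 had 18.6 ± 8.30 and 26.4 ± 8.69 TPM. The Sox2 groups overlapped, and its log2 fold change of 0.52 ranged from 0.07 to 0.97 with 1 library left out. General pluripotency genes had a camera adjusted p = 0.670, and 4 were higher and 2 lower when adjusted over the list alone. Dppa2 (51.0 and 40.6 TPM in wild type, 17.9 and 20.2 TPM in Stk40-/- cells) and Dppa4 (70.4 ± 4.60 and 45.0 ± 1.91 TPM) were the lower ones, and both lie on chromosome 16, whose genes were lower in general as given below. Their log2 fold changes, -1.22 and -0.63, were larger in size than the median of that chromosome, -0.19. Naive pluripotency genes went both ways (14 tested, 5 positive and 9 negative, camera adjusted p = 0.477, mixed fry adjusted p = 0.0851). In 4 of them both Stk40-/- libraries lay above both wild-type libraries, and in 2 below. Dppa5a, among the lower ones, had 308 ± 25.5 and 155 ± 6.69 TPM. The later mesoderm lists did not pass camera in the main setting (adjusted p = 0.0884 for paraxial, 0.0634 for lateral plate and cardiac, and 0.0634 for blood and endothelial genes), but each was called lower under some alternatives. Paraxial genes were called at a mean of at least 5 TPM (adjusted p = 0.00361) and without mitochondrial and ribosomal protein genes (0.0207). Lateral plate and cardiac genes were called without those genes (0.0428) and without Stk40-/- library 2 (0.0454), and blood and endothelial genes at a mean above 0 TPM (0.0114). Of these lists only the blood and endothelial genes passed the mixed fry test (adjusted p = 0.0245). Msgn1, a presomitic mesoderm factor, was at 90.6 and 7.22 TPM in wild type and at 0.975 and 0 TPM in Stk40-/- cells, so that wild-type library 1 set most of its mean. Hand1 had 2.69 ± 0.590 and 1.996 ± 0.685 TPM, with overlapping groups. Its log2 fold change of -0.31 ranged from -0.55 to -0.07 with 1 library left out. Mesp1, Tbx6, Kdr, Pdgfra, Sox17 and Gata6 lay below the expression filter. Endoderm markers did not pass either (adjusted p = 0.670 for definitive and 0.885 for extraembryonic endoderm).

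Lists of genes linked to JUN did not pass camera at the RNA level, but AP-1 subunit genes (adjusted p = 0.0215) and genes associated with JUN binding (adjusted p = 0.0320) passed the mixed fry test for change in either direction. The mixed test does not compare a list with other genes, and 18 of 37 lists passed it, so passing is not particular to JUN. In 8 of the 20 JUN-associated genes both Stk40-/- libraries lay above both wild-type libraries, and in 6 below. Over all tested genes the groups did not overlap in 44.0%. AP-1 subunit genes had a camera adjusted p = 0.119 over 11 tested members, with Fos at 4.43 ± 0.586 and 1.49 ± 0.334 TPM and Junb at 20.7 ± 0.843 and 16.7 ± 0.763 TPM. Genes associated with JUN binding had a camera adjusted p = 0.882 over 20 members, of which Gja1, a gap junction gene, passed adjusted over the list alone (191 and 207 TPM in wild type, 279 and 297 TPM in Stk40-/- cells). Genes of the COP1 ubiquitin ligase, which targets c-JUN for degradation, and of its partners and substrates passed neither test (camera adjusted p = 0.650, mixed fry adjusted p = 0.0863, 16 members). Trib1, a pseudokinase gene of the same family as Stk40, had 6.78 ± 0.637 TPM in wild type and 16.5 ± 3.72 TPM in Stk40-/- cells. The cell cycle list had a camera adjusted p = 0.0634, and Ccnd1 had 53.5 ± 1.08 and 63.0 ± 2.40 TPM.

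**Figure D2:**
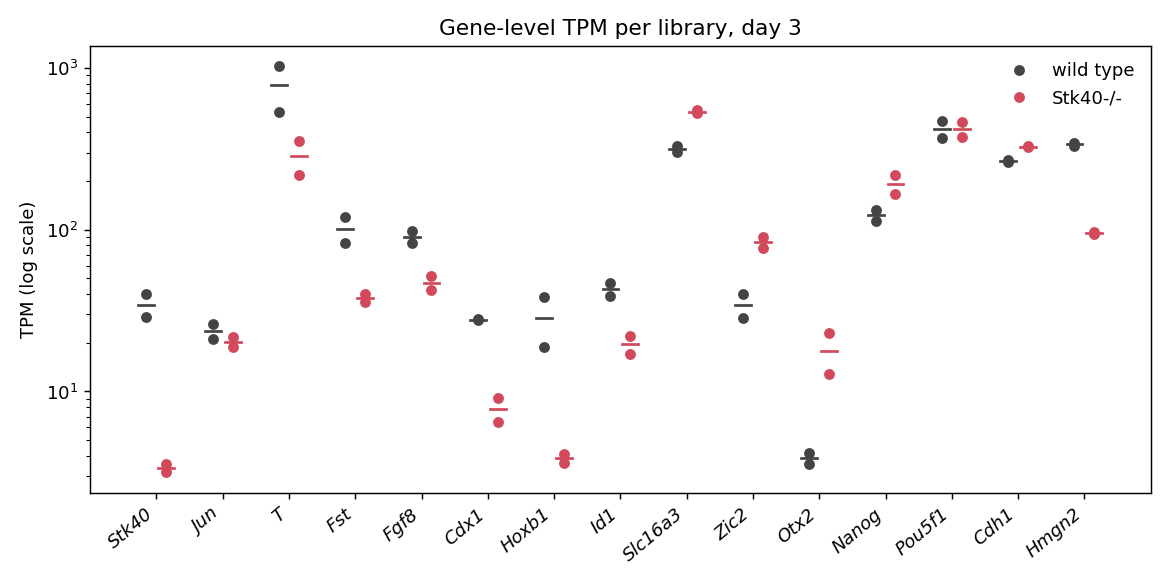
TPM per library on a log axis for 15 named genes, with wild type in grey and Stk40-/- in red, points for the 2 libraries of each group and a bar for their mean. Stk40 lies at 3.54 and 3.17 TPM in the Stk40-/- libraries, and the Jun libraries of both groups overlap.

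Across all genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05 among 15739 tested (smallest adjusted p = 0.114). At an unadjusted p under 0.05 there were 1020 higher and 710 lower, a balance that depended on the scaling. It turned to 737 higher and 881 lower with quantile normalization, 670 and 956 with median-of-ratios rescaling, and 690 and 814 with the length trend removed, the last chosen after seeing the data. In 44.0% of tested genes the groups did not overlap, against 33.3% by chance. In an alternative chosen after seeing the data, TPM was recomputed over protein-coding genes and these alone were filtered and tested (13017 genes). There 1 gene was called higher, Gm3424 (limma adjusted p = 0.0150), and 2 lower, Hmgn2 (0.0144) and Plp2 (0.0182). Hmgn2, a nucleosome-binding protein gene, had 338 ± 11.6 TPM in wild type and 94.8 ± 1.97 TPM in Stk40-/- cells. The 12 genes with the smallest p in each direction did not pass the threshold over all genes. Among the higher ones were Slc16a3, Fgfbp1 (29.1 ± 4.95 and 86.6 ± 8.83 TPM), Gm28037 (139 ± 6.99 and 462 ± 117 TPM), Pard6a (13.4 ± 1.58 and 31.6 ± 2.25 TPM) and Gm10093 (7.87 ± 0.308 and 20.7 ± 0.360 TPM). The other 7, namely Gm3424, Gm25464, Scarna6, Gm22711, AC131759.2, Mir669h and Gm38364, are listed at 0 in both wild-type libraries, so no fold is given. Trav6-3, AC173345.2 and Gm23876 are listed at 0 in both Stk40-/- libraries, and Gm13597 was at 0 and 0.451 TPM there. Short RNAs and genes with near-identical copies are uncertain, because reads can be divided among them. The same may hold for Gm28037 (chromosome 16, 55966343 to 55980721). Protein-coding genes starting at 55966275 and 55973883 had log2 fold changes of -0.70 and 0.17, and sharing of reads with them was not tested.

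Of the 12 lower genes, 6 lie in the first 10 Mb of chromosome X. They were Plp2 (958 ± 53.9 and 425 ± 4.78 TPM), Nudt11 (63.8 ± 3.62 and 21.3 ± 0.220 TPM), Clcn5 (78.7 ± 6.53 and 25.5 ± 0.796 TPM), Rbm3 (1466 ± 5.05 and 768 ± 62.2 TPM), Ebp (66.9 ± 3.93 and 22.8 ± 1.95 TPM) and Hdac6 (79.2 ± 2.49 and 32.7 ± 1.81 TPM). By position in the mouse build GRCm38, all 35 protein-coding genes with a mean of at least 5 TPM between 6047453 and 9663003 on X had negative fold changes, with a median of -1.17, and in 33 the groups did not overlap. The 329 such genes on the rest of X had a median of 0.11. On chromosome 16 the 328 genes had a median of -0.19, against 0.08 for 9713 genes outside these 2 regions, and 79.9% of them lay below that median. These regions were noticed after the values were seen. Without them camera called 4 lists higher and 10 lower, compared with 4 and 7 over all genes, with Nodal and activin target genes (adjusted p = 0.0386) added, and lateral plate and cardiac and immediate early genes added just under the threshold.

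**Figure D3:**
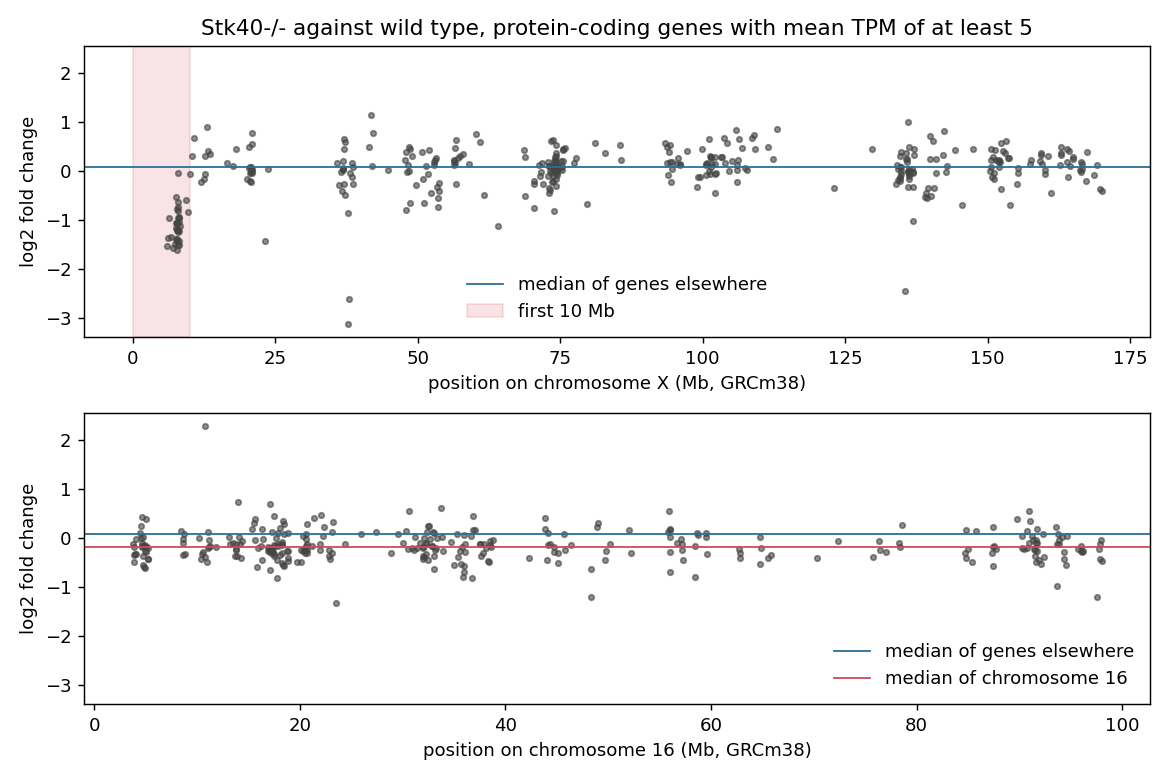
Log2 fold change of Stk40-/- against wild type for protein-coding genes with a mean of at least 5 TPM, by position in GRCm38 on chromosome X (top) and chromosome 16 (bottom), with the median of genes elsewhere in blue, the first 10 Mb of X shaded and the chromosome 16 median in red. The 35 genes in the shaded part have a median of -1.17 and chromosome 16 a median of -0.19.

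Whether the libraries separated by genotype depended on the genes taken. Over all tested genes the Pearson correlation was 0.930 between the wild-type libraries and 0.944 between the Stk40-/- libraries, and it ranged from 0.922 to 0.935 between libraries of different genotype. Over the protein-coding genes among them it was 0.971 and 0.978 within genotypes and ranged from 0.964 to 0.971 between them, with the wild-type value above the highest of these by less than the rounding. Genes are not independent replicates. Wild-type library 2 stood apart in its short RNAs. RNAs of the class misc_RNA, which holds the 7SL and 7SK RNAs, made up 2.89% of its TPM, against 0.159% in wild-type library 1 and 0.116% and 0.187% in the Stk40-/- libraries. Without that library camera called 7 lists lower and 3 higher, but not the same lists: BMP targets (adjusted p = 0.161) and neuroectoderm (adjusted p = 0.0536) were no longer called, and FGF and ERK targets were called lower (adjusted p = 0.0278).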

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

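Limma called 0 genes in each direction under every alternative planned before the data were examined. With TPM recomputed over protein-coding genes only, with or without robust eBayes, it called 1 higher and 2 lower. The cause of these calls was not tested. That alternative was chosen after seeing the data, as were the removal of 2 regions and of the length trend. Leaving out each library gave 0 genes in both directions, and a lone library was assumed to vary like the other group. The Stk40 level kept its direction (-3.34 to -2.78). For gene lists, camera called 7 lower and 4 higher. With an estimated correlation it called 0 and 0, with fry 1 and 0, and with TPM recomputed without mitochondrial and ribosomal protein genes 12 lower. Leaving out each library gave 1 to 3 lists higher and 7 to 8 lower. The primitive streak list kept its direction throughout, with mean log2 differences from other genes of -1.50 to -0.79 without 1 library, and lost its call with an estimated correlation (-1.15) and with fry (mean -1.11). The estimated correlation also found 0 of 37 simulated shifts.

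The labels give no shared litter or day for equal replicate numbers, and deviations of same-numbered libraries correlated at 0.0893 over 2 pairs. With the replicate block limma called 0 genes higher and 0 lower, and camera 11 lists lower and 4 higher, adding paraxial (adjusted p = 0.0445), lateral plate and cardiac (0.0409), immediate early (0.0409) and Nodal and activin genes (0.0296).

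Camera also called 8 further lists under at least 1 alternative: lower for paraxial, lateral plate and cardiac, blood and endothelial, primordial germ cell, immediate early, Nodal and activin, and FGF and ERK genes, and higher for the cell cycle. Some results that were not called changed direction, and the cause was not tested. The direction in camera, which compares a list with other genes and weighs genes by their spread, can differ from that of the mean. Leaving out 1 library gave -0.42 to 0.12 for Eomes and -0.18 to 0.17 for Pou5f1. Mean differences from other genes then ranged from -0.059 to 0.10 for general pluripotency, -0.053 to 0.18 for definitive endoderm, -0.088 to 0.16 for extraembryonic endoderm, -0.11 to 0.056 for JUN-associated genes, -0.37 to 0.00033 for FGF targets, -0.055 to 0.044 for epithelial junctions, -0.013 to 0.093 for the integrated stress response, -0.062 to 0.0047 for heat shock genes, -0.27 to -0.14 for imprinted genes, -0.038 to 0.18 for mitochondrial genes and -0.33 to 0.11 for histones. For JUN-associated genes the direction in camera turned from higher to lower in 3 further settings, while the mean difference was already -0.025 in the main setting. It was -0.051 without mitochondrial and ribosomal protein genes, -0.025 with the block and -0.063 with protein-coding genes. In fry, which does not compare a list with other genes, means were 0.10 for definitive endoderm, 0.075 for extraembryonic endoderm, -0.14 for the somite clock, 0.027 for COP1 genes and 0.010 for heat shock genes. Depth is unknown, so its limits cannot be stated.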

Other observations

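Genes outside the comparisons above are given first, chosen after their values were seen. The imprinted growth genes H19 (137 TPM in wild type and 34.3 TPM in Stk40-/- cells), Igf2 (27.0 and 8.15 TPM) and Cdkn1c (37.8 and 13.2 TPM) passed limma adjusted over the imprinted list alone, as 3 lower members, beside 3 higher ones, Nnat (36.2 and 56.0 TPM), Grb10 (50.7 and 66.8 TPM) and Rian (720 and 850.1 TPM), while the list as a whole did not pass camera (adjusted p = 0.477) but passed the mixed fry test (adjusted p = 0.0211). Meg3 was at 310 and 362 TPM. On X outside the low segment, the reproductive homeobox genes Rhox5, Rhox6 and Rhox9 had 276, 20.2 and 16.6 TPM in wild type and 151, 1.54 and 2.16 TPM in Stk40-/- cells. Gm28438, a pseudogene in a block of mitochondrial sequence on chromosome 1, was at 1884 and 2354 TPM in wild type and at 124 and 0.0309 TPM in Stk40-/- cells, and reads shared with mitochondrial genes make it uncertain. Xist and the Y-linked gene Ddx3y stayed below 1 TPM in all 4 libraries.

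In the tests of the 3 patterns that follow, only the histone test was written before its result was seen, and the others were chosen after. The first pattern is the low segment at the start of X. A scaling factor shared by all genes of a library would move them alike, whereas the segment median was -1.17 and that of genes outside both regions 0.08. Transcript length correlated with the fold change across 10076 genes (Spearman 0.248), but with the length trend removed the segment median was -1.12. A loss of 1 copy or silencing of this segment in the Stk40-/- line is a candidate explanation, as a hypothesis. Loss of 1 copy of a pair would by itself give -1 relative to other genes. Relative to them the segment lay at -1.25, and at -1.175 or lower in each pair of a Stk40-/- and a wild-type library. Such a loss alone falls short of these values. The segment median was -1.10 or lower in each pair of libraries, which an effect of Stk40 loss would give as well. A difference between the lines therefore cannot be told apart from the genotype. No DNA was analysed here, so the number of X copies in either line is unknown.

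The second pattern is chromosome 16. With the length trend removed the chromosome stayed at -0.27 relative to other genes. Its median was the lowest of 20 chromosomes. The difference from other genes was -0.20 or lower in each pair of libraries. A gain of the chromosome in some wild-type cells, or a loss in some Stk40-/- cells, may give such a shift, and this cannot be told apart from an effect of the genotype because each genotype may come from 1 line.

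The third pattern is wild-type library 2, where the 7SL gene Rn7s1 was at 10739 TPM against 365, 157 and 531 TPM in the other libraries, Rn7sk at 5859 against 381, 281 and 411 TPM, and Rmrp at 150 against 4.28, 8.18 and 16.2 TPM. Weaker poly(A) selection may raise such RNAs, and would raise replication-dependent histone mRNAs, which lack a poly(A) tail. These were higher by a median of 0.27 on the log2 scale (SE 0.18, 17 genes), between the bounds set in advance, so the test leaves it open. The summed TPM of the histone list was 145 in this library, against 122 in wild-type library 1 and 172 and 134 in the Stk40-/- libraries. Loss of long transcripts was left open too. The Spearman correlation across genes between transcript length and the library's deviation was -0.181, against -0.129 for wild-type library 1 and 0.197 and 0.162 for the Stk40-/- libraries. Its sign followed genotype, and each deviation was taken from the mean of the other libraries, of both genotypes. Wild-type library 1 lacked the rise in short RNAs, so this correlation cannot separate loss of long transcripts in library 2 from the genotype difference. No biological explanation was tested, since the design separates no group within wild type.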
